A study of Mus musculus with 6 samples.

How the data were processed

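Gene expression was measured in 6 mouse mammary tumour cell lines, 3 wild type for Akt1 and 3 knocked out for Akt1, each hybridised to a single array. Per the labels' protocols, the lines were grown out of tumours that arose in mice carrying an ErbB2 oncogene under the MMTV promoter, a viral promoter active in mammary epithelium, and fibroblasts were reduced by a short plating step before culture. Total RNA was amplified with a whole-transcript kit that primes with a chimeric DNA/RNA primer, and the product was fragmented and labelled with biotin, per the labels' protocols. The labels do not say whether each line came from a separate animal, so p-values measure the spread between these lines.

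The authors deposited log2 expression values for 45101 probe sets on each array, in a workbook sheet and again in a value table of the series, and both agree to within 5.0e-09. How the arrays were scanned, corrected for background, summarised and normalized is not given in the sources used here. The deposited values ran from 1.62 to 14.26 log2 units, and the array medians lay between 5.41 and 5.50, so the arrays had been brought to a common scale before deposit. The authors also deposited a p-value for each probe set, which equals that of an unadjusted equal-variance two-sample test to within 3.2e-09. A log2 difference (knockout minus wild type) and a B score were deposited for the 5881 probe sets with a deposited p-value under 0.05 and for no probe set above it, and a gene symbol for 5611 of them. A signed fold score per probe set and a sheet of KEGG pathways with the authors' pathway p-values came with them. The tool and the background behind those pathway p-values are not given in the sources used here.

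The gene symbols therefore cover probe sets already chosen by their p-value, which limits what can be named. Leaving out 64 control probe sets, 5604 probe sets carried a symbol, with 4485 distinct symbols. Of these symbols, 3146 are current in the RefSeq gene table of the GRCm38.p6 assembly, 959 match a single synonym there and 380 match none and were kept as deposited, giving 4462 genes. The assembly was used for names, for the chromosome of a gene and for the order of neighbours. A gene with several named probe sets was represented by the probe set of highest mean over the 6 arrays, and other named probe sets that went the opposite way are given where such a gene is named.

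The deposited values were analysed as they stand with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, knockout minus wild type, no covariate), for all 45037 probe sets that are not controls. Benjamini-Hochberg adjustment ran over all of these probe sets, with an adjusted p under 0.05 as the threshold. The plan had been to adjust over named genes, but names exist only at small p-values and an adjustment over them would be too lenient. A count at unadjusted p under 0.05 with at least a 2-fold change is given beside the adjusted count, because the authors' sheets use such a limit. For single measures of 3 against 3 arrays an exact two-sided permutation test was used, whose smallest p is 0.1. The number of arrays, 3 per group, limits the precision of every difference; the median standard error was 0.18 log2 units.

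Altogether 35 lists of genes (pathways, cell type markers and complexes) were fixed before the data were examined, as were the groups, the tests, the alternatives listed as planned and the rule for naming genes. That rule always includes Akt1, Akt2 and Erbb2. It then takes up to 12 genes in each direction with the largest difference among those with an adjusted p under 0.05 and no overlap between the groups, filled up by smallest unadjusted p among non-overlapping genes with at least a 2-fold change, which are described as not passing. In that part, predicted and clone-derived genes with names in Gm or Rik are counted and not named. Up to 4 members of smallest p are named for each list, whatever their symbol. Lists were tested with limma's camera (preset correlation 0.01) where at least 5 members were named, which left 20 lists. The test set a list's named members against all other named genes, so that it asks about direction among genes already at a deposited p under 0.05. The count of members that passed is also given adjusted over the list alone, with members lacking a named probe set counted as not passing. A gene is named as soon as any of its probe sets had a deposited p under 0.05. That choice among the probe sets of a gene was not corrected for, so the counts over the list alone are lenient. The remaining 15 lists are given as counts. The directional set test fry was not run, because list members had been chosen by their p-values.

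The fit and the list test were tested on simulated arrays with the means of the 45037 probe sets and limma's prior variances, in 10 runs with 200 changed probe sets each. True log2 differences of 0.5, 1, 2 and 4 were recovered for 0.2%, 10.4%, 75.4% and 94.6% of probe sets, and 5.25% of the calls were false. With no change simulated, 0 probe sets were called on average. In separate runs, among simulated probe sets chosen by their own p, camera placed 4% of random lists under an unadjusted p of 0.05. The simulated probe sets varied independently of each other, so these runs cannot show how camera behaves where list members are correlated. The alternatives tried were the series value table, quantile normalization again, median centring, cyclic loess, a filter on the dimmest 30% of probe sets, an intensity trend, robust moderation, array weights, the mean of a gene's named probe sets, no moderation, other thresholds, a covariate for the 3' to 5' gap of Gapdh, other forms of the list test, and leaving out each line in turn. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for reading, checks and plots.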

Results

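The series holds 6 arrays of mouse mammary tumour cell lines driven by the ErbB2 oncogene, a receptor tyrosine kinase amplified in part of human breast cancers. Lines 31, 101 and 102 were wild type for Akt1 and lines 72, 75 and 116 were knocked out for it. Akt1 encodes a serine/threonine kinase that acts downstream of phosphoinositide 3-kinase, and the comparison asks how gene expression in these tumour cells differs without it. Expression is given in the authors' deposited log2 units, and all differences are knockout minus wild type.

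Akt1 itself was lower in every knockout line. Its brighter probe set averaged 9.94 ± 0.20 log2 units in the wild-type lines and 4.53 ± 0.13 in the knockout lines (SD, n = 3 each), a 42.8-fold difference (limma, adjusted p = 0.000405). Its other probe set went from 7.01 ± 0.23 to 3.99 ± 0.10, an 8.12-fold difference (adjusted p = 0.0106). The exact permutation p was 0.1 for either probe set, the smallest that 3 against 3 arrays allow. Both probe sets match the genotype in the labels; where they lie relative to the deleted part of the gene is not given in the sources used here. Akt2, a close relative of Akt1, averaged 8.24 ± 0.37 in the wild-type and 7.55 ± 0.15 in the knockout lines, a difference that did not pass (adjusted p = 0.208). Erbb2 had no named probe set and was not analysed here.

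**Figure D1:**
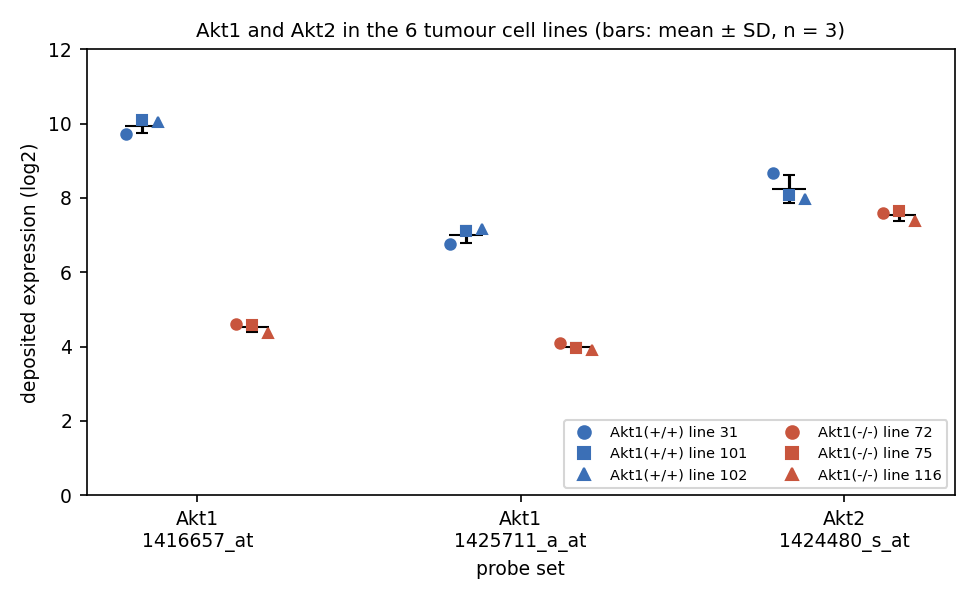
Deposited log2 expression (vertical axis) of the named probe sets of Akt1 and Akt2 (horizontal axis) in each of the 6 lines, with group means and SD bars (n = 3). The 3 knockout lines average 4.53 and 3.99 for the Akt1 probe sets, against 9.94 and 7.01 in the wild-type lines, while Akt2 averages 7.55 against 8.24.

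Beyond Akt1, the genes that passed were mostly lower in the knockout lines. Of 45037 probe sets tested, 48 passed at an adjusted p under 0.05, representing 45 genes, with 44 probe sets lower and 4 higher. Every one of the 48 differed at least 2-fold. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, fell by 2.63 log2 units from 6.39 ± 0.52 to 3.76 ± 0.20 (SD, n = 3; adjusted p = 0.0422). AA407452, listed as Zfp800 in current annotation, fell by 3.37 (adjusted p = 0.0295). Eif4g1, the scaffold of the cap-binding translation initiation complex, fell by 2.08, and Inppl1, which encodes the inositol phosphatase SHIP2, fell by 1.72 with a group SD of at most 0.04. Crebbp, a histone acetyltransferase, fell by 1.79 and Jarid1a (now Kdm5a), a histone demethylase, fell by 1.94. Immt, which organises mitochondrial cristae, fell by 1.85, as did the adiponectin receptor gene Adipor2. Birc6, an inhibitor of apoptosis, fell by 1.97, Zc3h13, a component of the RNA methylation machinery, by 1.81 and M6prbp1 (now Plin3), a lipid droplet protein, by 1.76; the adjusted p of these 9 genes lay between 0.0295 and 0.0398.

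Only 2 genes eligible for naming rose past the threshold. AB056442 rose from 2.62 ± 0.23 to 4.94 ± 0.20 log2 units (adjusted p = 0.0295), with a second probe set 1.88 higher. It was dim in the wild-type lines, where its probe sets averaged 2.62 and 2.55, below the lower quartile of every array, 3.71 to 3.81. With dim probe sets left out, 1 probe set was called higher, against 4 with all probe sets. Map3k8, which encodes the MAP kinase kinase kinase Tpl2, rose by 1.21 (adjusted p = 0.0403). The next 10 genes by unadjusted p did not pass, with adjusted p between 0.05 and 0.0736. The milk protein gene Csn1s1 had the largest difference among them, 13.06 ± 0.62 against 10.05 ± 0.65, or 8.06-fold higher in the knockout lines (adjusted p = 0.0614). Thoc1, a subunit of an mRNA export complex, was 1.66 higher, and Sdc4, a cell surface heparan sulphate proteoglycan, 1.49 higher. Rpgrip1 was 1.45 higher, H2-Q1, a class I histocompatibility gene, 1.38 higher and D6Ertd109e 1.26 higher. Chic2, Fignl1, Asb13 and Gnpda2 were between 1.05 and 1.12 higher.

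Agreement between the named probe sets of these genes was partial. Symbols exist only at a deposited p under 0.05, so any probe set of these genes that did not differ could not be seen here. Crebbp had probe sets with differences of -1.93 and -0.16 beside the brightest one at -1.79, and a second Jarid1a probe set differed by -0.86 beside -1.94. Second probe sets of Eif4g1, Birc6 and AA407452 differed by -1.02, -1.09 and -1.54, in the same direction and smaller. Zc3h13 had others at -1.65 and -0.68, and second probe sets of Thoc1, Asb13 and Gnpda2 were 0.75, 0.88 and 0.31 higher.

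**Figure D2:**
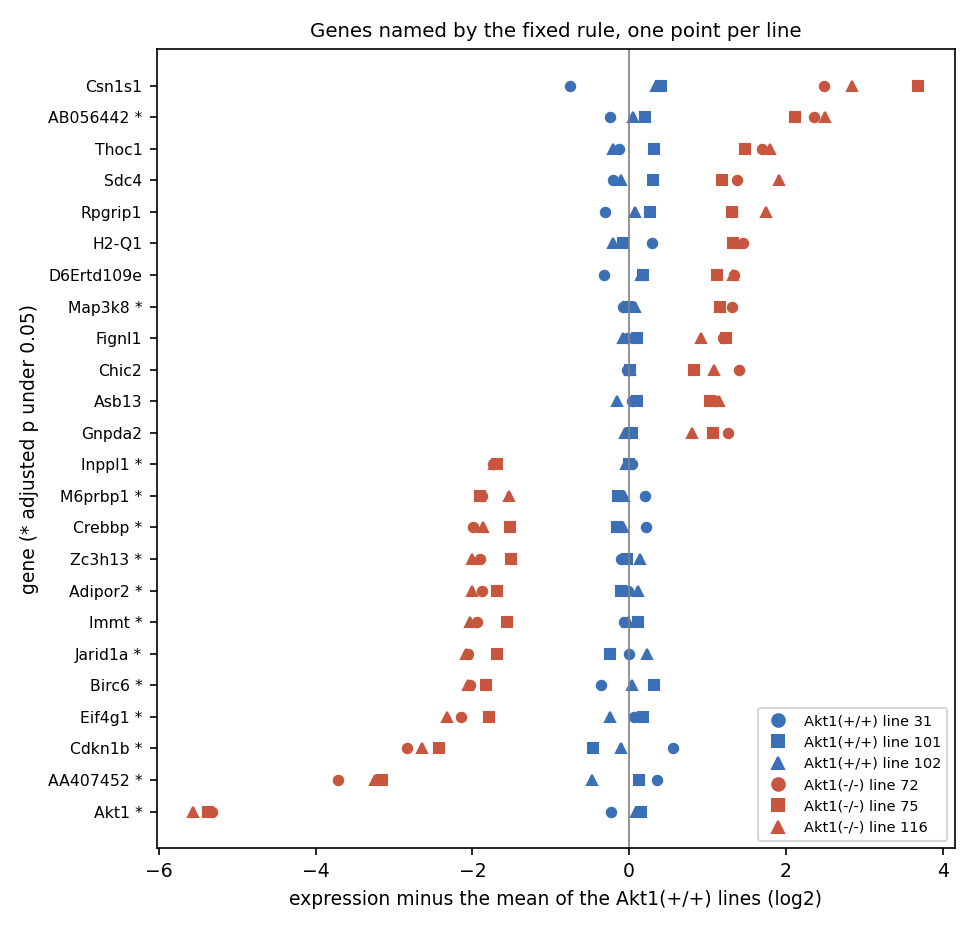
Expression of each named gene in each line minus the mean of the 3 wild-type lines (horizontal axis, log2), one row per gene (vertical axis); an asterisk marks an adjusted p under 0.05. In every row the 3 knockout lines lie on one side of the 3 wild-type lines, from 5.42 lower on average for Akt1 to 3.01 higher for Csn1s1.

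At the looser limit of an unadjusted p under 0.05 with at least 2-fold change, 1263 probe sets differed, 962 lower and 301 higher in the knockout lines. Without the fold limit 6919 probe sets had an unadjusted p under 0.05, where chance gives about 2252, and 9855 probe sets (21.88%) had no overlap between the groups, where chance gives 10%. The authors' deposited table lists 5881 probe sets at its own p under 0.05, 2777 higher and 3104 lower, and 953 with more than a 2-fold change, 183 higher and 770 lower. The authors' 5881 and 953 include 12 and 8 control probe sets, which the other counts given here leave out. The 48 calls depended on the full set of lines: without knockout line 75 there were 327 (all of the 48 among them) and 2094 at the looser limit, without wild-type line 31 there were 2, and without any other line 1. The mean of a gene's named probe sets left 4 calls. Median centring ended the calls of Cyp51, a sterol demethylase gene (adjusted p = 0.062), Cdkn1b (adjusted p = 0.0559) and Crebbp (adjusted p = 0.0513), and a filter on dim probe sets (adjusted p = 0.0529) or an intensity trend (adjusted p = 0.0618) that of Map3k8. Quantile normalization (adjusted p = 0.0523) and the dim filter (adjusted p = 0.0519) also ended that of Cyp51. Over the alternatives run for single genes the adjusted p ranged from 0.037 to 0.18 for Cdkn1b, from 0.0289 to 0.18 for Crebbp, from 0.0291 to 0.18 for Map3k8 and from 0.037 to 0.165 for Cyp51.

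Correlations between arrays were 0.969 to 0.981 within a genotype and 0.962 to 0.979 between genotypes, across probe sets, which are not independent. Knockout line 75 correlated best with wild-type line 101 (0.979). On the first principal component, with 35.7% of the variance, the wild-type lines 31, 101 and 102 scored 61.5, 39.2 and 16.3, and the knockout lines 72, 75 and 116 scored -52.6, 8.08 and -72.5, so that every wild-type line lay above every knockout line.

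All 10 named members of the 31-gene cell cycle list were higher in the knockout lines, with a median difference of 0.75 log2 units (camera adjusted p = 0.00928). The list was not called with its estimated correlation of 0.076 in place of the preset 0.01 (camera adjusted p = 0.62). The named members include the replication licensing genes Mcm6 (1.13 higher, 10.33 ± 0.38 against 9.20 ± 0.25), Mcm4 (0.92 higher) and Mcm7 (0.68 higher) and the mitotic cyclin gene Ccnb1 (0.80 higher). All 10 passed adjusted over the list alone and 0 passed over all probe sets (limma), with 10 at an unadjusted p under 0.05. The last count follows largely from the naming, here and for every other list, since symbols exist only at a deposited p under 0.05. The adjusted p of the list ranged from 0.000702 to 0.62 over the alternatives.

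All 10 named members of the 30-gene ribosomal protein list were lower in the knockout lines, with a median of -0.80 log2 units (camera adjusted p = 0.0426). This list too was not called with its estimated correlation, 0.415 in place of the preset 0.01 (camera adjusted p = 0.62). Rpl13 averaged 9.25 ± 0.19 against 10.92 ± 0.55 in wild type, and Rps24, Rpl18 and Rps7 differed by -1.18, -1.22 and -0.83. Of the 10, 3 passed adjusted over the list alone and 0 over all probe sets (limma), with 9 at an unadjusted p under 0.05. The call also ended on ranks (adjusted p = 0.146), with median centring (0.05), with dim probe sets left out (0.0651), with the mean of a gene's probe sets (0.0638) and without wild-type line 31 (0.0816), knockout line 72 (0.0657) or knockout line 116 (0.0502), where the adjusted p over all alternatives ranged from 0.0123 to 0.62. No other list was called. The knockout arrays, on which these lists differed, also had a lower signal of the bioC spike-in control (-1.27) and a wider Actb 3' to 5' gap (0.43 log2 units).

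**Figure D3:**
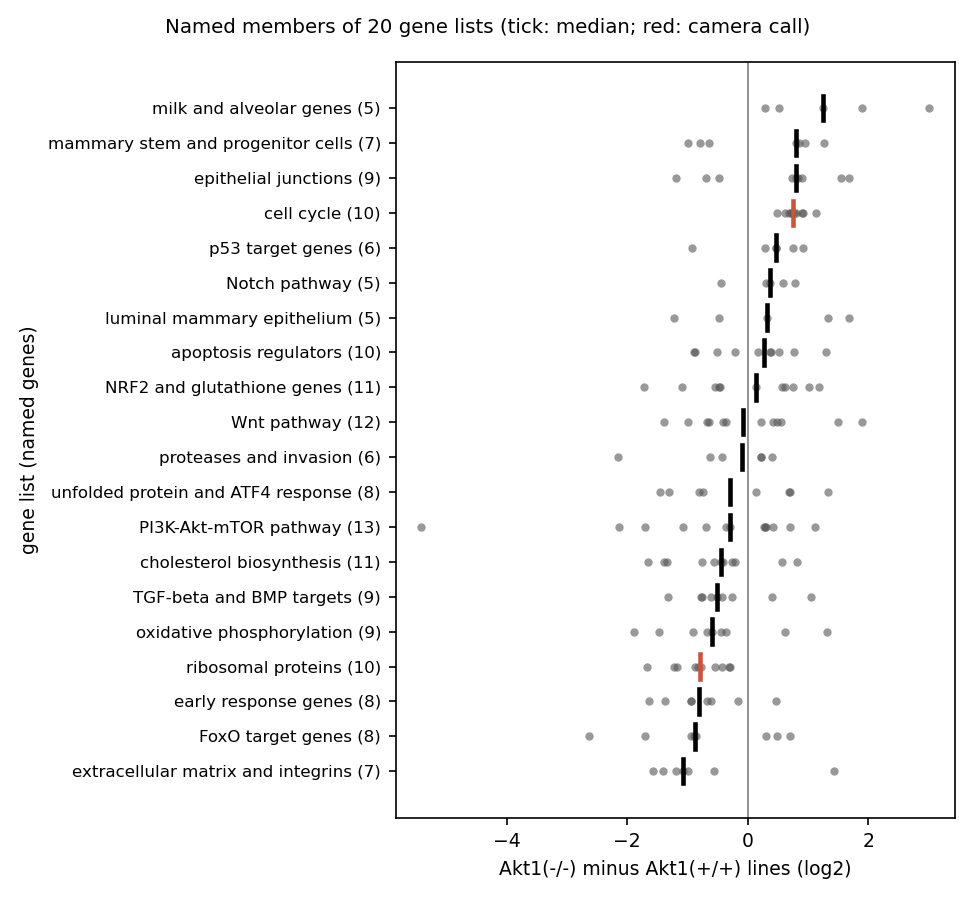
Difference between knockout and wild-type lines (horizontal axis, log2) of each named member (points) of the 20 tested lists (vertical axis, number of named members in parentheses), with the list median as a tick. The cell cycle list (median 0.75) and the ribosomal protein list (median -0.80) are the 2 called by camera with the preset correlation, and neither was called with an estimated correlation (adjusted p = 0.62 for both).

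Milk protein and alveolar genes were the next group in rank. All 5 named members of 18 were higher in the knockout lines, with a median of 1.25 log2 units, and the list was not called (camera adjusted p = 0.0889). Besides Csn1s1, Xdh, needed for milk fat secretion, averaged 10.31 ± 0.52 against 8.42 ± 0.80, Csn1s2a was 1.25 higher and Csn2 0.51 higher; 3 of the 5 passed adjusted over the list alone and 0 over all probe sets (limma), with 4 at an unadjusted p under 0.05. The list was called without wild-type line 101 (adjusted p = 0.0385), and its adjusted p ranged from 0.0385 to 0.62 over the alternatives. Luminal markers went both ways, with 3 of 5 named members higher (camera adjusted p = 0.695). Xbp1 and Cldn3 were 1.33 and 1.67 higher, whereas Trps1 and Cldn7 differed by -1.22 and -0.48, and Xbp1 alone passed adjusted over the list alone and 0 over all probe sets (limma, 4 at an unadjusted p under 0.05). Of the basal markers, Krt5 was 0.60 higher and Itgb4 differed by -0.56, neither passing adjusted over the list alone (limma, both at an unadjusted p under 0.05). Among progenitor markers, 4 of 7 were higher (camera adjusted p = 0.812); Lrp6 was 2-fold lower and Sox9 differed by -0.79, and Tacstd1 (now Epcam) and Aldh2 were 0.80 and 1.26 higher, all 7 passing adjusted over the list alone and 0 over all probe sets (limma, 7 at an unadjusted p under 0.05).

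Few markers of other cell types that such cultures could hold were named, which does not show whether those cells were present, since names exist only for probe sets that differed. None of the 16 fibroblast markers was named. Plvap of the endothelial list differed by -1.40 and Lipe of the adipocyte list by -0.62. Of the leukocyte list Cd8a was 0.87 higher in the knockout lines, and Laptm5 and Coro1a differed by -0.79 and -0.69. Cd8a was dim, at 3.71 ± 0.26 in the wild-type and 4.59 ± 0.17 in the knockout lines. Lipe, Cd8a and Laptm5 passed adjusted over their lists alone, and none of these 5 over all probe sets (limma, all 5 at an unadjusted p under 0.05).

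Within the phosphoinositide 3-kinase pathway, 13 of 31 genes were named, 6 higher and 7 lower in the knockout lines (camera adjusted p = 0.812). Akt1 was the sole member to pass over all probe sets in the chosen probe sets, and 5 passed adjusted over the list alone. The upstream kinase gene Pdpk1 differed by -1.07 (adjusted p = 0.0593) and the catalytic subunit gene Pik3ca was 0.70 higher. Probe sets of Gsk3b, an Akt substrate, disagreed: the one that passed fell by 1.20 (adjusted p = 0.0422), while 2 others were 1.11 and 0.80 higher. Targets of FoxO transcription factors, which Akt holds out of the nucleus, were 3 higher and 5 lower among 8 named (camera adjusted p = 0.613). Besides Cdkn1b, the lower members were Klf6 (-0.95), Sod2 (-0.86), Bcl2l11 and Irs2, and Pik3ca was 0.70 higher; 6 passed adjusted over the list alone and Cdkn1b over all. Of ErbB ligands and regulators, Nrg2 averaged 4.32 ± 0.72 against 7.09 ± 0.23 (adjusted p = 0.0558), Btc and Dusp4 were 0.89 and 0.64 higher and Lrig1 differed by -1.49; Nrg2 and Btc passed adjusted over the list alone and 0 members over all probe sets (limma, 4 at an unadjusted p under 0.05).

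Cell survival genes went in both directions. Of 10 named apoptosis regulators 6 were higher (camera adjusted p = 0.695), and Bcl2l1 alone, at -0.87, passed adjusted over the list alone. Birc3 was 0.51 higher, 2310024N18Rik (now Cflar) 1.29 higher, and Bcl2l11, a death-promoting BH3 protein, differed by -0.89. Of 6 named p53 targets 5 were higher (camera adjusted p = 0.278), among them Rrm2b, Btg2 and Ccng1 at 0.75, 0.47 and 0.91; Trp53 itself differed by -0.93 and alone passed adjusted over the list alone. No member of either list passed over all probe sets (limma), with 8 and 5 at an unadjusted p under 0.05.

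Most named genes of the cholesterol, fatty acid and oxidative phosphorylation lists were lower in the knockout lines. The cholesterol and oxidative phosphorylation lists were tested and not called, and the fatty acid, glycolysis and hypoxia lists had too few named genes to test. In cholesterol biosynthesis 9 of 11 named genes were lower (median -0.45, camera adjusted p = 0.273). Cyp51 fell by 1.65 log2 units (adjusted p = 0.0479). Of the alternatives run for each single gene, 4 ended that call, apart from leaving out lines. The Gapdh covariate fit ended it too, as its sole call was Akt1. Tm7sf2 differed by -1.34, while Stard4 was 0.82 higher, and 6 members passed adjusted over the list alone. All 4 named fatty acid synthesis genes were lower, led by Scd1 (-1.81) and Elovl6 (-1.45), with Dgat1 at -0.64 and Acaca at -0.38; 0 passed adjusted over the list alone (limma) and 4 had an unadjusted p under 0.05. In oxidative phosphorylation 7 of 9 were lower (median -0.59, camera adjusted p = 0.277), with Ppargc1a, a coactivator of mitochondrial biogenesis, at 7.26 ± 0.50 against 9.15 ± 0.30, Ndufa4 at -1.47, Sdhb at -0.91 and Atp5a1 at 1.31; 8 passed adjusted over the list alone. Of glycolysis genes Pfkp differed by -1.14 and alone passed adjusted over the list alone, and Pdk1, Ldha and Pgk1 were 0.85, 0.38 and 0.27 higher. Of hypoxia response genes Hif1a differed by -1.24 and Higd1a and Car12 were 1.16 and 0.37 higher, none passing adjusted over the list alone (limma, 4 at an unadjusted p under 0.05). Car12 was dim, at 3.57 in the wild-type and 3.94 in the knockout lines. The redox enzyme gene Txnrd1 fell by 1.72 (adjusted p = 0.0346) in the NRF2 and glutathione list, where Gclm differed by -1.10 and Hmox1 and Srxn1 were 1.18 and 0.61 higher. Of its 11 named members 6 were higher, with a median of 0.13 and a mean of 0.00 (camera adjusted p = 0.985). Stress response genes were split evenly, 4 higher and 4 lower (camera adjusted p = 0.996), with Xbp1 and Hspa5 1.33 and 0.69 higher and Cebpb and Hsp90b1 at -1.45 and -0.81. Another probe set of Cebpb was 0.76 higher, and the mean of both differed by -0.35. The median of that list was -0.30 and its mean -0.18, while the camera direction was higher, and 6 passed adjusted over the list alone. Over all probe sets Cyp51 and Txnrd1 alone passed among these lists (limma).

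The authors' deposited pathway sheet names 12 KEGG pathways with 145 gene listings, 126 lower and 19 higher. In the authors' deposited table the smallest pathway p was 0.00032 for tight junction, followed by 0.0011 for focal adhesion and 0.00132 for adherens junction, and mTOR signalling (0.0341) had 6 genes listed, all lower. Actb is listed in 4 of these pathways with a signed fold of 3.23, while the other Actb probe sets in the authors' deposited table have signed folds of -2.03 to -2.92.

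Control probe sets differed between the genotypes in part. The bioC spike-in, a bacterial transcript added in a fixed amount before hybridization, averaged 9.08 ± 0.15 log2 units on the wild-type arrays and 7.81 ± 0.18 on the knockout arrays (SD, n = 3), with no overlap (exact permutation p = 0.1). The spike-ins bioB, bioD and cre differed by 0.06, -0.19 and 0.03, all with overlap. The gap between the 3' and 5' probe sets of Actb, a measure of RNA integrity and of amplification, was 3.48 ± 0.05 in the knockout lines and 3.05 ± 0.22 in wild type, with no overlap (exact permutation p = 0.1), and that of Gapdh 3.52 ± 0.35 against 2.77 ± 0.63 (exact permutation p = 0.2).

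**Figure D4:**
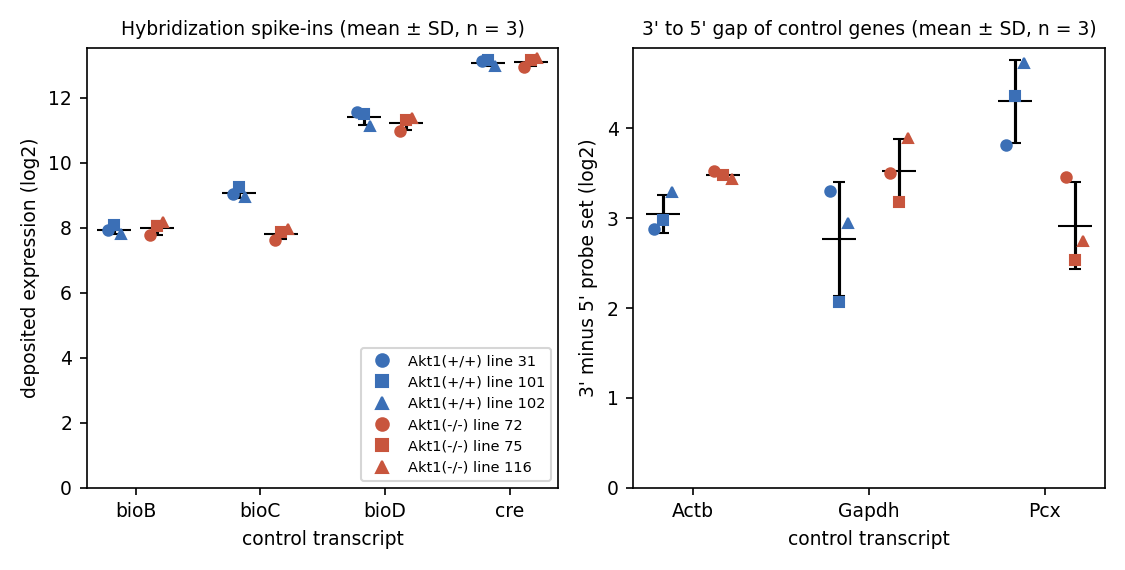
Left, deposited log2 expression (vertical axis) of 4 hybridization spike-ins; right, the log2 gap between 3' and 5' probe sets of Actb, Gapdh and Pcx, for each line, with group means and SD bars (n = 3). The bioC spike-in averages 7.81 on the knockout and 9.08 on the wild-type arrays, and the Actb gap 3.48 against 3.05.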

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

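The tests of the batch and of the splits of the arrays for both counts of probe sets were chosen after their results had been seen, and the cyclic loess and Gapdh covariate fits were added after the data had been seen, with their limits set before their own results.

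Of 17 control measures, some of which share probe sets, 9 separated the genotypes without overlap, where chance gives 10% with 3 against 3 arrays. The ends and middles among them were those of Actb (-0.97 at the 3' end, -1.54 in the middle, -1.40 at the 5' end), of Gapdh (-0.98 in the middle, -0.79 at the 5' end) and of Pcx at the 3' end (-1.37). The bioC spike-in differed by -1.27 log2 units between knockout and wild-type arrays. The Actb 3' to 5' gap differed by 0.43. The Pcx 3' to 5' gap differed by -1.38, and because the 5' probe set of Pcx averaged 4.85 and 4.87, this gap follows the 3' probe set, which averaged 7.78 in the knockout and 9.15 in the wild-type lines.

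Large differences ran mostly towards lower expression in the knockout lines, with 76.2% of the 1263 probe sets at unadjusted p under 0.05 and at least 2-fold change. An uneven scaling of the arrays is argued against: after cyclic loess 74.2% were still lower (95% binomial interval 71.6 to 76.6, too narrow as far as probe sets are correlated), above the 60% set as the limit beforehand. Uneven RNA integrity as the Gapdh gap measures it is argued against as the whole cause, with 66.4% lower (interval 64.1 to 68.7) when that gap was a covariate, although that fit called 1 probe set at an adjusted p under 0.05, and the Actb gap, which separated the genotypes, was not fitted. A hybridization batch cannot be told apart from genotype, since the bioC difference of -1.27 may mark a different control mix or day for the 3 knockout arrays. Loss of Akt1 stays open beside it. Gene length stays open too, after an early look of which no value was kept. Another split of the arrays (wild-type lines 31 and 102 with knockout line 116) leaned as far to one side, with 77.4% of its 433 probe sets.

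The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 48 probe sets at an adjusted p under 0.05 and the highest other split 0, so that 1 of the 10 splits gave as many. At unadjusted p under 0.05 with at least 2-fold change it gave 1263 and the highest other split 852 (wild-type lines 31 and 101 with knockout line 75), again 1 of the 10. Camera called 2 lists on the real split and up to 4 on another, and 5 of the 10 splits called at least 2. Each split was tested within the named genes, which were chosen by their p on the real split. The other splits are therefore not a like comparison for the lists, and no conclusion is drawn from these counts.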

How the results depend on the processing

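Cyclic loess, the Gapdh covariate, Fisher's test of direction and camera run on the statistics of the whole fit were chosen after seeing the data, as was the unmoderated test for Akt1; the other alternatives were planned. Akt1 stayed under the adjusted threshold in every alternative run (adjusted p from 0.000294 to 0.0371), with differences of -5.53 to -5.35 log2 units when a line was left out and -4.22 as the mean of both probe sets. No named gene and no list median turned direction in any alternative that gave it a value.

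The count of 48 probe sets was the least stable result. It was 239 with array weights, 92 after cyclic loess, 4 with the mean of the named probe sets of a gene, 3 without variance moderation and 1 with the Gapdh covariate, and 1 to 327 when a line was left out. At adjusted p under 0.1 it was 776 and under 0.2 it was 2873, so many probe sets lie just past the threshold. Quantile normalization again gave 47, with 44 of the 48 among them. The count at the looser limit lay between 946 and 1689 in the other settings and between 1184 and 2094 when a line was left out. Lower probe sets made up 66.4% to 80.7% of it, against 76.2%.

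The number of lists called by camera, 2 as reported, was 0 with an estimated correlation and 1 with median centring, dim probe sets left out, the mean of the named probe sets or ranks. It was 1 to 3 when a line was left out: 1 without wild-type line 31, knockout line 72 or knockout line 116 and 3 without wild-type line 101. The cell cycle list was lost with the estimated correlation alone. The cause of these shifts was not tested, apart from fewer arrays when a line is left out. The planned test fry was not run, and signal over background is not given for these arrays, so a bound for dim probe sets was not set.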

Other observations

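The comparisons by chromosome, between probe sets of the same gene and around Akt1 were chosen after the data had been seen, and the rotation test after chromosome 19 had been seen to lie furthest towards lower. Of 8 named members of the 23-gene early response list 7 were lower in the knockout lines (median -0.81 log2 units, camera adjusted p = 0.22), led by the phosphatase gene Dusp5 (-1.38, adjusted p = 0.0521), Ier2 (-1.64), Klf6 (-0.95) and Jun (-0.67), and 7 passed adjusted over the list alone. Of 7 named matrix and integrin genes 6 were lower (median -1.08, camera adjusted p = 0.273), with Lama4, Lamc1 and Itgb4 at -1.41, -1.08 and -0.56 and Itgb5 2-fold lower, and Lama4 and Itgb5 passed adjusted over the list alone. Of 9 named epithelial junction genes 6 were higher (camera adjusted p = 0.356): Pkp2, a desmosomal plakophilin, averaged 6.87 ± 0.66 against 5.33 ± 0.37, Tacstd1 and Dsg2 were 0.80 and 0.73 higher, and E-cadherin, Cdh1, differed by -0.70, with 8 of the 9 passing adjusted over the list alone. Of invasion genes 3 of 6 were lower (camera adjusted p = 0.985), with the membrane protease gene Mmp15 at 7.19 against 9.35, Ctsd and Ctsb at -0.63 and -0.43 and Mmp10 at 0.40, and Mmp15 alone passed adjusted over the list alone. Mesenchymal genes were 1 higher and 3 lower, with Tgfb2 1.05 higher and Zfhx1b (now Zeb2), Tgfbr2 and Tgfb1 at -0.85, -0.77 and -0.27. No gene of these lists passed over all probe sets (limma), and 7, 7, 9, 4 and 3 members in the order given had an unadjusted p under 0.05.

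Signalling lists went both ways. The Wnt list had 6 higher and 6 lower (camera adjusted p = 0.996): Wnt5b and Wnt5a were 1.90 and 1.49 higher, Lrp6 was 2-fold lower and Tcf7l2 differed by -1.39, while the median was -0.08, the mean 0.05 and the camera direction higher. Of 9 TGF-beta and BMP targets 7 were lower (camera adjusted p = 0.356), with Ski, Smad3 and Tmepai (now Pmepa1) at -0.76, -0.52 and -1.32 and Tgfb2 1.05 higher. Of 5 Notch genes 4 were higher (camera adjusted p = 0.34), with Notch2, Hey2 and Rbpsuh (now Rbpj) 0.59, 0.78 and 0.30 higher and Dll4 at -0.44. Hey2 (2.88 in the wild-type and 3.66 in the knockout lines) and Rbpsuh (3.22 and 3.52) averaged below the lower quartile of every array, 3.71 to 3.81. Adjusted over the list alone, 5 Wnt, 2 TGF-beta and BMP and 0 Notch genes passed, and over all probe sets none (limma, 11, 8 and 5 at an unadjusted p under 0.05). None of the 36 interferon-stimulated genes was named. Antigen presentation genes were 2 higher and 2 lower, with H2-T23 (adjusted p = 0.0506, the sole one to pass adjusted over the list alone) and Tapbp at -1.07 and -0.86 and B2m and H2-K1 0.74 and 0.16 higher. Of chemokine genes Cx3cl1 differed by -1.78 and Il23a, Ccl2 and Ccl7 were 0.65, 0.38 and 0.21 higher. Ccl7 was dim, at 3.84 in the wild-type and 4.05 in the knockout lines. Histone genes were 2 and 2, with Hist2h2aa1 and Hist1h3a at -1.34 and -1.19 and H2afz and H1f0 0.86 and 0.65 higher. No chemokine or histone gene passed adjusted over the list alone (limma, 3 and 4 at an unadjusted p under 0.05). The Y-linked genes Jarid1d, Eif2s3y and Uty averaged 3.33 or less in either group, with 0 at an unadjusted p under 0.05 (limma).

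Of 3918 named protein-coding genes placed on the GRCm38.p6 assembly, all chosen by their p-values, 53% were lower in the knockout lines, but on chromosome 19 it was 140 of 168 (83.3%, median -0.77 log2 units, Fisher's exact test, which takes genes as independent, with Benjamini-Hochberg adjustment over 20 chromosomes, adjusted p = 8.84e-16), and on chromosome 1 it was 83 of 245 (33.9%, adjusted p = 5.35e-09); 10 chromosomes passed. Names matched through a synonym can place a gene wrongly, and among the 3010 genes with a current symbol 108 of 130 were lower on chromosome 19 (83.1%, adjusted p = 7.06e-11) and 8 chromosomes passed. A single cluster on chromosome 19 is argued against, since the lowest of its 4 equal parts had 81% lower, but runs of like-directed neighbours with no tie to a chromosome stay open: in 3.8% of 3917 rotations of the directions along the gene order some chromosome had as high a share, and these overlap so much that about 23 are independent (95% binomial interval 0.11% to 21.9%). Another candidate explanation is a different number of copies of whole chromosomes in the knockout lines, which would lower most genes of chromosome 19 alike; it was not tested, as no DNA data were analysed here, and GC content was not tested either, while gene length stays open after an early look of which no value was kept. Chromosome 19 holds 3 of the 39 placed called genes (Capn1, Gbf1 and Sf3b2, named after their values were seen), and without it 78.1% of the placed genes with at least 2-fold change were lower, against 79.5% with it.

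Probe sets of the same gene often disagreed. Of 890 genes with at least 2 named probe sets 243 had probe sets in opposite directions, 96 of them with differences beyond 0.5 log2 units both ways, and 25.6% of 1478 pairs were opposite. Probe sets that match several transcripts were judged by their name endings alone. Of 794 pairs of plain _at probe sets 29.6% were opposite, against 20.3% of 428 pairs with an _s_at or _x_at member, a ratio of 1.46. This argues against probe sets with an _s_at or _x_at ending as the whole source. Pairs with another ending, such as _a_at, and no _s_at or _x_at member were in neither group, so the test does not cover them. Chance calls among single probe sets may account for part: among 240 pairs with both unadjusted p under 0.005 the share was 12.5% (95% binomial interval 8.59 to 17.4), which spans the 10% limit set beforehand. Alternative transcripts and distance from the 3' end stay open, since probe positions were not used here.

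Of the 88 protein-coding genes within 50 genes on either side of Akt1 on chromosome 12, 20 had a named probe set (22.7%, against 18.1% of all protein-coding genes; Fisher's exact p = 0.267), 9 of them higher and 11 lower.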
